A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

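Chromatin immunoprecipitation followed by sequencing measures where DNA is bound to a histone carrying a given modification. Per the labels' protocols, BY4741 cells in mid-log growth were fixed with formaldehyde, nuclear chromatin was cut with micrococcal nuclease, fragments were pulled down with an antibody against H3K4me2 or H3K4me3, and Illumina libraries were made. Micrococcal nuclease cuts between nucleosomes, so stretches without nucleosomes give few fragments whatever their modification. The series has 3 samples: 1 H3K4me2 library, 1 H3K4me3 library and 1 input, which has no list of its own. Groups were taken from the sample titles.

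Per the submitters' processing notes, CASAVA 1.8.2 and MACS 1.4.2, a peak caller, were used with the genome build sacCer3; their settings, the aligner, the treatment of reads with several matches and the control given to the peak caller are not given in the sources used here. The authors deposited 1 list of peaks per library, with start, end and summit of each peak and 3 values. Per the file headers, these are the number of tags in the peak, a whole-number count that was not normalised; a fold enrichment, a ratio whose background the headers do not name; and a p-value column. Its values all lie above 50, so it was read as the score that MACS 1.4 writes, -10 times the log10 of p; the authors deposited this score without stating its scale. A peak's fold and score are the authors' own values and were used to describe, rank or filter peaks within a list. Fold values of the 2 lists were not compared with each other, since they depend on the depth of each library. The numbers of peaks depend on it too.

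Genes came from a RefSeq table of the R64 assembly, which is the assembly that sacCer3 names. It lists 6477 genes, of which 6002 are nuclear and protein-coding. Of their lengths 96.4% are multiples of 3, so they are spans from start codon to stop codon without untranslated regions, and "gene start" means the start codon. The table has no strand, which was taken from the W or C in the systematic name. Chromosome lengths are not in it, so shares of the genome refer to the span up to the last annotated gene or peak, and the centromere was placed in the gap between the last left-arm and first right-arm gene. All 628 members named in the 23 gene lists were found.

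A gene counted as marked when peaks covered at least 50% of its first 500 bp (of the whole gene in the 893 shorter genes). Classes, profiles (10 bp steps, genes of at least 1000 bp), centres of the covered bases and the last 500 bp (genes of at least 1500 bp) were computed from the peak intervals with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. With 1 library per mark no test between marks was run and no p-value is given. Shares have exact (Clopper-Pearson) 95% intervals, and a share of 0 is given with the limit that 3 counts would set. Profile positions and median distances have bootstrap intervals over genes, which are not independent replicates. Overlaps and gene starts were compared with 1000 circular shifts within each chromosome. Gene lists were compared with 10000 random lists of the same size matched on gene length in 10 bins; a list stands apart when at most 2.5% of random lists are as high or as low. These comparisons describe these libraries. The functions were tested on simulated peaks placed on 2195 real genes: 800 of 800 marked starts, a shift of 300 bp between marks and a planted list were recovered.

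The design, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The rule names, per mark, the 10 genes whose start windows hold the peaks of highest fold, the 5 strongest starts with a single mark, all spindle checkpoint genes, the 4 genes altered in BY4741, and for each list the 2 members with the highest H3K4me3 fold and the 2 longest without H3K4me3. The name patterns also caught RPP1, an RNase P subunit, among ribosomal proteins, COS111, which is no member of the COS family, among PAU and COS genes, and RPN4, a transcription factor, among proteasome genes. Alternatives were a score of at least 100, peaks at or above the median fold of their list, the same number of peaks in both lists, peaks of 500 bp around the summit, other overlaps, other windows, isolated start windows and genes of at least 3000 bp. A limit on the false discovery rate was planned and not run, because the lists have no such column. Chosen after a first look at the values were the 2.5% limit for calling a list, the position at 50% of the maximum, the gap between arms as a stand-in for the centromere with its intergenic background, the list of widest peaks, the map of the GAL cluster, the summit positions and the ribosomal protein list without RPP1. The planned 500 bp flanks of centromeres were not run. Mitochondrial genes were left out, and transposons were not analysed here.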

Results

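Chromatin from budding yeast (Saccharomyces cerevisiae) of the laboratory strain BY4741, growing in rich glucose medium, was digested with micrococcal nuclease and immunoprecipitated with antibodies against histone H3 dimethylated (H3K4me2) or trimethylated (H3K4me3) at lysine 4. The series holds 3 samples, 1 library per mark and 1 input without antibody, and the data are the lists of enriched regions (peaks) of both marks. The design asks where each mark lies across the genome. The H3K4me2 list held 2998 peaks with 1492318 tags inside them, and the H3K4me3 list held 3714 peaks with 1644589 tags. The median peak held 453 H3K4me2 tags (range 170 to 1776) or 391 H3K4me3 tags (range 128 to 2689). The sequencing depth of each library is unknown, because the lists give tags within peaks alone. With 1 library per mark no difference between the marks has a replicate check. Exact intervals on counts cover counting error only, and not that of peak calling. They treat genes or peaks as independent, although neighbouring genes can share a peak.

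Both marks covered a large part of the 16 nuclear chromosomes, and most H3K4me2 peaks lay over an H3K4me3 peak. H3K4me2 peaks covered 27.9% of the annotated span of 12053405 bp, and H3K4me3 peaks covered 32.0%. The median width was 1049 bp for H3K4me2 (quartiles 851 and 1325 bp) and 972.5 bp for H3K4me3 (quartiles 797 and 1184 bp). The authors' fold enrichment per peak had a median of 2.64 in the H3K4me2 list (range 1.84 to 4.09) and 3.09 in the H3K4me3 list (range 1.85 to 4.79). Of the H3K4me2 peaks, 2625 (87.6%, exact 95% interval 86.3 to 88.7) overlapped an H3K4me3 peak by at least 1 bp, and 373 did not. Of the H3K4me3 peaks, 2594 (69.8%, 68.3 to 71.3) overlapped an H3K4me2 peak, and 1120 did not. When the peaks were moved by random distances along their chromosomes, 1000 times, the overlap was 52.7 to 57.5% for H3K4me2 and 45.7 to 50.1% for H3K4me3, so both observed values lay above every shifted list. Both libraries may share the input as control, and part of the overlap above chance may come from it. The bases under both marks made up 47.4% of the bases under either. By chromosome, H3K4me3 coverage ran from 24.9% on chromosome I to 36.3% on chromosome XIV, and H3K4me2 coverage from 23.8 to 31.5%.

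H3K4me3 lay at the beginning of genes and H3K4me2 further into them. Along the 3592 protein-coding genes of at least 1000 bp, H3K4me3 was most frequent 290 bp after the start codon, where it covered 69.6% of genes. H3K4me2 was most frequent 570 bp after it, at 60.9% of genes. At the start codon itself 64.9% of genes were under an H3K4me3 peak and 23.4% under an H3K4me2 peak. Upstream, both profiles dipped, H3K4me3 to 21.9% at 270 bp before the start codon and H3K4me2 to 5.82% at 190 bp before it. At 1000 bp into the gene the order was the other way round, with 25.9% of genes under H3K4me3 and 49.5% under H3K4me2. The profile fell to 50% of its maximum at 910 bp for H3K4me3 (bootstrap 95% interval over genes 890 to 920) and at 1300 bp for H3K4me2 (1280 to 1340).

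**Figure D1:**
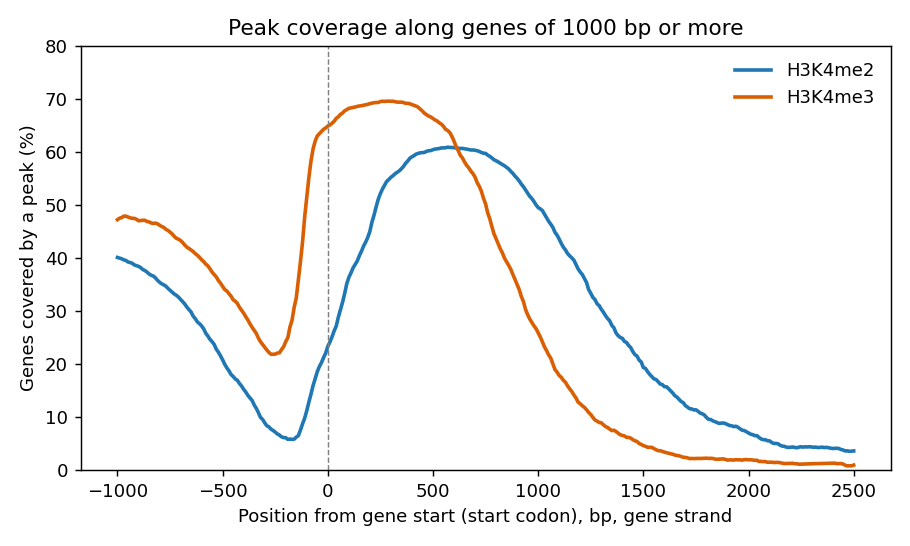
Share of the 3592 protein-coding genes of at least 1000 bp that lie under a peak (vertical axis, %) by distance from the start codon on the gene's own strand (horizontal axis, bp), for H3K4me3 (orange) and H3K4me2 (blue), 1 library each. A gene contributes up to its end; the H3K4me3 curve peaks at 290 bp and the H3K4me2 curve at 570 bp.

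The order of the marks held within single genes. Among 2248 genes of at least 1500 bp, 1240 carried both marks somewhere in the gene, and the centre of the H3K4me2-covered bases lay downstream of the H3K4me3 centre in 1197 of them (96.5%, lower bound of the exact 95% interval 95.4), upstream in 34 and at the same place in 9. The median distance was 198 bp (bootstrap 95% interval 190 to 207, quartiles 108 and 310 bp). Over the last 500 bp of these 2248 genes a mark was less frequent, with H3K4me2 in 386 genes (17.2%, 15.6 to 18.8) and H3K4me3 in 113 genes (5.03%, 4.16 to 6.01). Over the first 500 bp the counts were 1140 genes (50.7%) and 1575 genes (70.1%). With every peak set to 500 bp around its summit, the median distance was 298 bp. The same trimming left H3K4me2 over 2.94% and H3K4me3 over 1.96% of gene ends. With untrimmed peaks in genes of at least 3000 bp the shares were 3.04 and 1.52%, so the share of marked ends depends on peak width and gene length.

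Most gene starts carried H3K4me3, fewer carried H3K4me2, and H3K4me2 without H3K4me3 was the rarest class. Of 6002 nuclear protein-coding genes, 3880 (64.6%, exact 95% interval 63.4 to 65.9) had H3K4me3 over at least 50% of their first 500 bp, against 31.1 to 34.4% when gene positions were shifted at random. H3K4me2 met the same rule in 2613 genes (43.5%, 42.3 to 44.8), against 26.7 to 29.8% in shifts. Both marks were present at 2307 starts (38.4%), H3K4me3 alone at 1573 (26.2%), H3K4me2 alone at 306 (5.10%) and neither at 1816 (30.3%). Of the 1573 starts with H3K4me3 alone, 361 genes (22.9%) had H3K4me2 over at least 1 bp of the gene, either below the limit in the start window or beyond it. Genes with both marks were longer (median 1395 bp) than genes with H3K4me3 alone (1041 bp) or neither (987 bp).

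The strongest H3K4me3 peaks over gene starts included those of the bromodomain proteins BDF1 (YLR399C, chromosome XII, 919536 to 921596), at 4.79-fold with 1221 tags, and BDF2 (YDL070W), at 4.50-fold with 775 tags. The transcription factor gene MOT3 (4.72-fold), MIX17 (4.70-fold), the translation elongation factor gene EFB1 (4.63-fold), the mRNA-binding protein gene NAB2 (4.60-fold), RPL16A (4.48-fold), SCS2 (4.43-fold), RPS19B (4.41-fold) and ATP14 (4.41-fold) completed the first 10. EFB1, NAB2, RPL16A, RPS19B and ATP14 were also the 5 strongest among starts with H3K4me3 alone; in EFB1 and NAB2 an H3K4me2 peak reached into 28.2 and 27.8% of the window, below the limit. The strongest H3K4me2 peak, at 4.09-fold with 1092 tags, spanned the starts of the convergent genes CAR2 (ornithine transaminase, YLR438W, chromosome XII, 1012501 to 1013775) and LSM3. It was followed by those of TPO2 (3.86-fold), PST2 (3.83-fold), MIR1 (3.74-fold), PRX1 (3.73-fold), PIL1 (3.63-fold), SRO9 (3.61-fold), SNF2 (3.56-fold) and NUP53 (3.54-fold), all of which carried H3K4me3 as well. Among starts with H3K4me2 alone the strongest were YJR115W (3.21-fold), TPO4 (3.19-fold), PPH21 (3.18-fold), MBB1 (3.18-fold) and HOR7 (3.15-fold). A peak that spans neighbouring starts counts for each of them, here and in the gene lists below. NNF1 and RSM7, named in different lists, share the same H3K4me3 peak (3.99-fold, chromosome X, 636963 to 639103).

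The series concerns the spindle assembly checkpoint, which holds back anaphase until every chromosome is attached, so its genes were examined one by one. H3K4me3 covered the starts of 8 of 11 checkpoint and passenger genes (72.7%), and H3K4me2 those of 4 (36.4%). H3K4me3 alone marked MAD1 (YGL086W, 3.05-fold, 376 tags), MAD2 (YJL030W, chromosome X, 387657 to 388247, 3.12-fold, 227 tags), MAD3 (YJL013C, 2.62-fold, 218 tags) and the kinase gene MPS1 (YDL028C, 3.39-fold, 345 tags). The H3K4me3 peaks at MAD2 and MAD3 had scores of 94.89 and 68.61, below the alternative limit of 100. Both marks lay over BUB3 (YOR026W, H3K4me3 3.98-fold with 1362 tags), SGO1, SLI15 and CDC20, the activator that the checkpoint restrains. The H3K4me3 peak at BUB3 ran from 378092 to 380713 and began upstream of the gene start at 379781. Its tags are therefore not those of BUB3 alone and do not rank this gene against the others. BUB1, BIR1 and the Aurora kinase gene IPL1 had neither mark over any base of the start window. Random lists of 11 genes matched on gene length held H3K4me3 in 36.4 to 90.9% of members (middle 95%) and H3K4me2 in 18.2 to 81.8%, so this list did not stand apart for either mark. With both lists cut to the same number of peaks the H3K4me3 count was 5, and with a score of at least 100 the H3K4me2 count was 2.

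Among the other mitotic lists, spindle and microtubule genes lay above random lists for both marks and cyclin and mitotic regulator genes for H3K4me2, and the remaining lists lay within the random range. Of 23 spindle and microtubule genes 22 carried H3K4me3 (95.7%, random lists 52.2 to 87.0%), among them ASE1 (4.15-fold) and the beta-tubulin gene TUB2 (3.59-fold), with CIN2 the exception. The ASE1 peak had a score of 62.39, below the alternative limit of 100, and 174 tags, against 727.85 and 758 tags at TUB2. H3K4me2 lay at 17 of the 23 starts (73.9%, random 30.4 to 69.6%), a value that was within the random range under 5 of 7 alternative settings. The H3K4me3 value was within it under 2 of 7. Of 15 cyclin and mitotic regulator genes 13 carried H3K4me2 (86.7%, random 26.7 to 80%, within the range under 3 of 7 alternatives). H3K4me3 was carried by 14 (93.3%, at the upper edge of the random range and outside it under 1 of 7 alternatives). CLB3 (3.93-fold) and the phosphatase gene CDC14 (3.65-fold) had the strongest H3K4me3 of that list, and CLB6 had neither mark. Kinetochore genes were marked like random lists, with H3K4me3 in 21 of 32, including NNF1 and SPC34, and not in CEP3 or CTF13. The same held for the anaphase-promoting complex, with H3K4me3 in 9 of 15 (outside the random range under 1 of 7 alternatives), including CDC27 and CDH1 and not APC1 or APC2. It held for cohesin and separase too, with 7 of 10, including IRR1 and PDS1 and not ESP1 or PDS5. Of the 12 genes that place or remove H3K4 methylation or act in the histone H2B ubiquitination it requires, 9 carried H3K4me3, with LGE1 (4.05-fold) and SWD3 (3.70-fold) strongest; the demethylase gene JHD2 and SDC1 carried neither mark.

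Genes of ribosome production mostly carried H3K4me3, and cytosolic ribosomal protein genes carried almost no H3K4me2. Of 138 genes matched as cytosolic ribosomal proteins, 104 (75.4%; random lists 56.5 to 71.7%) had H3K4me3 over the start and 1 had H3K4me2 (0.725%; random lists 31.9 to 46.4%). That 1 gene was RPP1, an RNase P subunit caught by the name pattern; of the 137 others 75.2% had H3K4me3 and 0 had H3K4me2 over 50% of the window, which allows a share of up to 2.19%. Named after its values were seen, RPS0B had H3K4me2 (3.12-fold) over 7.2% of its window and 58.5% of the gene, and was the only 1 of the 137 with any. The H3K4me3 direction depends on the window: within the gene the list lay 11.1 percentage points above random lists, and over 500 bp on both sides of the start codon the difference was -21.1 points. RPL16A and RPS19B were the strongest, and RPL7A and RPL7B were the longest below the limit for H3K4me3, although a peak (3.5-fold, 316 tags) covered 48.6% of the RPL7A window. Many ribosomal protein genes have a near-identical second copy, and the treatment of reads that match both is not given in the sources used here. Mitochondrial ribosomal protein genes had H3K4me3 in 53 of 67 (79.1%; random 49.3 to 71.6%; within the range under 1 of 7 alternatives) and H3K4me2 in 13 (19.4%; random 23.9 to 44.8%; within the range under 3 of 7 alternatives), with MRP20 (4.13-fold) and RSM7 (3.99-fold) strongest and MRPL49 and MRPL25 without H3K4me3. Ribosome biogenesis genes had H3K4me3 in 60 of 62 (96.8%; random 58.1 to 80.6%), led by UTP25 (4.16-fold) and RRP14 (4.03-fold), and H3K4me2 in 30 (48.4%), inside the random range. UTP9 and NOP10 were the exceptions for H3K4me3.

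TCA cycle and ergosterol synthesis genes were marked more than random lists by both marks and proteasome genes by H3K4me3, while glycolysis and heat shock genes were not. All 14 genes of the TCA cycle, which oxidises acetyl groups in mitochondria, carried H3K4me3 (random 42.9 to 92.9%; within the range under 1 of 7 alternatives) and 13 carried H3K4me2 (92.9%; random 21.4 to 71.4%), with LSC1 (H3K4me3 3.74-fold) and MDH1 (3.61-fold) strongest. All 20 ergosterol synthesis genes carried H3K4me2 (random 30 to 75%) and 19 carried H3K4me3 (95%; random 50 to 90%), with ERG9 and ERG10 strongest and ERG28 under H3K4me2 alone; each of these 2 values was within the random range under 2 of 7 alternatives. Proteasome genes had H3K4me3 in 31 of 33 (93.9%, random 54.5 to 84.8%), with RPN3 (4.12-fold) and PRE6 (4.02-fold) strongest and RPN9 and RPN13 without it. They had H3K4me2 in 11 (33.3%), inside the random range and outside it under 1 of 7 alternatives. Glycolysis genes did not stand apart, with H3K4me3 in 15 of 20 (outside the random range under 1 of 7 alternatives), including PFK1 and PFK2. PDC5 had neither mark and PYK2 had H3K4me2 alone. Heat shock protein genes had H3K4me3 in 10 of 14, with SIS1 (4.39-fold) and SSA2 (3.93-fold) strongest; SSA3 had neither mark and SSA4 had H3K4me2 alone.

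**Figure D2:**
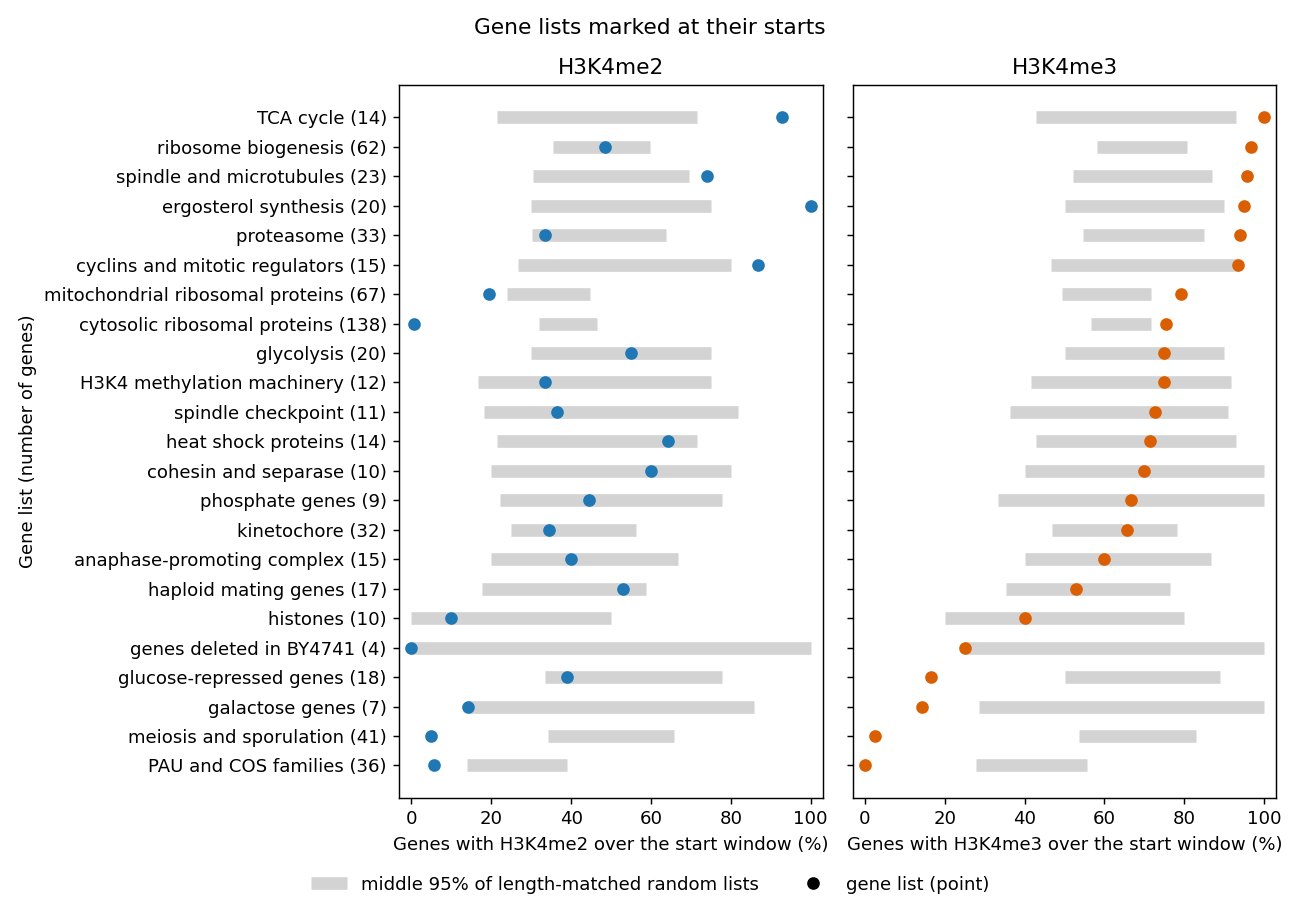
Share of each gene list with H3K4me2 (left, blue) or H3K4me3 (right, orange) over at least 50% of the first 500 bp of the gene (horizontal axes, %), with the number of genes in brackets; grey bars are the middle 95% of 10000 random lists of the same size matched on gene length. Cytosolic ribosomal protein genes sit at 0.725% for H3K4me2 and 75.4% for H3K4me3, and meiosis and sporulation genes sit at 4.88 and 2.44%.

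Gene lists that are repressed in haploid cells growing on glucose mostly lacked H3K4me3. Of 41 meiosis and sporulation genes 39 had neither mark, 2 had H3K4me2 (4.88%; random 34.1 to 65.9%) and 1 had H3K4me3 (2.44%; random 53.7 to 82.9%). SMK1, a sporulation kinase gene, carried both, while the long genes SPO22 and MSH5 carried none at their starts. The H3K4me3 peak covered 50.2% of the SMK1 window, just above the limit of 50%. Glucose-repressed genes had H3K4me3 in 3 of 18 (16.7%; random 50 to 88.9%), namely ICL1 (3.2-fold), FBP1 (3.12-fold) and SUC2, and H3K4me2 in 7 (38.9%), inside the random range. H3K4me2 alone lay over the maltose transporter gene MAL11 (2.65-fold), and ACS1 had neither mark at its start. Of 7 galactose genes, the repressor gene GAL80 (4-fold H3K4me3) carried both marks and the other 6 carried neither at the start. This share of 14.3% lay below random lists for H3K4me3 (28.6 to 100%; within the range under 2 of 7 alternatives) and within the random range for H3K4me2 (14.3 to 85.7%). The cluster on chromosome II held 1 peak of each mark, inside GAL10 (YBR019C, 276253 to 278352, minus strand). The H3K4me3 peak ran from 276909 to 277587 (2.62-fold, 233 tags) and the H3K4me2 peak from 276896 to 277859 (2.59-fold, 419 tags). Both lay just downstream of the start, at 276805 on the plus strand, of the annotated antisense transcript YNCB0008W. The cluster map was chosen after its values were seen.

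**Figure D3:**
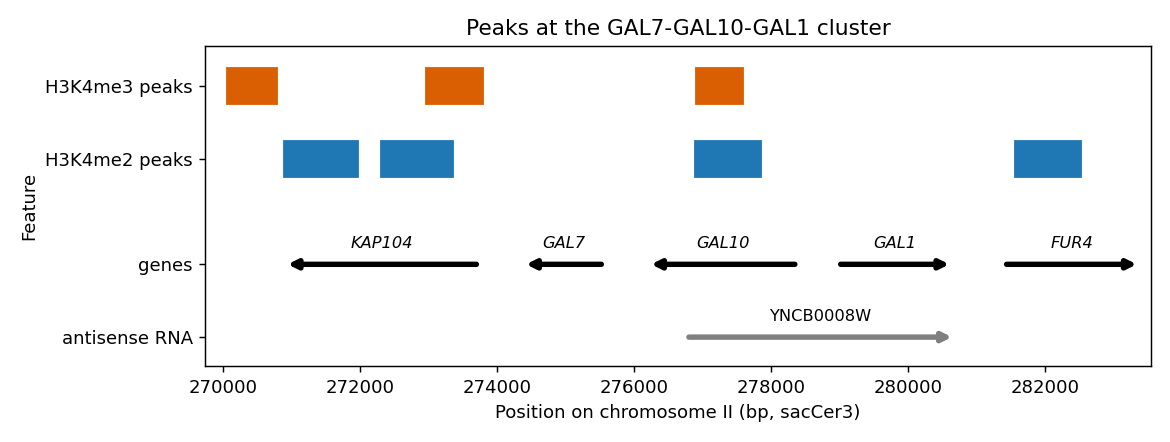
Map of the GAL7-GAL10-GAL1 cluster and its neighbours on chromosome II (horizontal axis, bp, sacCer3), with H3K4me3 peaks (orange), H3K4me2 peaks (blue), genes (black arrows) and the annotated antisense transcript YNCB0008W (grey arrow), each pointing in the direction of transcription. The only peaks from GAL7 to GAL1 lie inside GAL10, from 276896 to 277859 for H3K4me2 and from 276909 to 277587 for H3K4me3.

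The remaining lists showed further differences by gene. Of the PAU and COS families, most of whose near-identical members lie close to chromosome ends, 0 of 36 carried H3K4me3 (random 27.8 to 55.6%), which allows a share of up to 8.33%, and 2 carried H3K4me2 (5.56%; random 13.9 to 38.9%; within the range under 1 of 7 alternatives), namely COS9 and COS10. COS111, a gene outside these families that the name pattern also caught, is counted among the 36 and had neither mark. Reads from near-identical genes may not be placed uniquely, which was not measured here, so a missing peak there does not show a missing mark. Of 17 mating genes 9 carried both marks, and none carried a single one. STE6 (H3K4me3 3.71-fold) and STE5 (3.41-fold) were strongest, and FUS1 and the alpha-specific receptor gene STE3 had neither. Named after their values were seen, the a-specific genes STE2, STE6 and BAR1 carried both marks, while the a-specific genes MFA1, MFA2 and AGA2 carried neither. The alpha-factor genes MF(ALPHA)1 and MF(ALPHA)2 carried neither as well; BY4741 is of mating type a. Histone genes had H3K4me3 in 4 of 10, with the linker histone gene HHO1 (4.16-fold) and the variant gene HTZ1 (3.88-fold) strongest and HHT1 and HTA2 without either mark. Phosphate genes had H3K4me3 in 6 of 9, with SPL2 (3.75-fold) and PHO3 (3.21-fold) strongest. PHO89 had H3K4me2 alone and PHO11 had neither.

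The 23 lists and 2 marks gave 46 comparisons with random lists. H3K4me3 lay above the random range in 7 lists and below it in 4, and H3K4me2 above it in 4 and below it in 4. At most 5 of the 10000 random lists were as extreme for 5 of the 11 H3K4me3 values and 5 of the 8 H3K4me2 values.

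The chromosome ends and several silent or repeated regions held few peaks, and little of the centromeric gaps was covered. Within 20 kb of the ends of the annotated span H3K4me2 covered 7.08% of bases and H3K4me3 5.28%, against 29.0 and 33.5% in the rest of the genome. Near-identical genes lie there, and reads that match several places may be missing, so low coverage does not by itself show missing marks. As a stand-in chosen after a first look, since no centromere is annotated, the interval between the last gene of the left arm and the first of the right arm, which holds the centromere, had an H3K4me3 peak reaching into it on 6 of 16 chromosomes and an H3K4me2 peak on 2. H3K4me3 covered 4.10% of these bases and H3K4me2 0.806%, against 14.0 and 7.29% of 1332 other intergenic intervals of 630 to 2541 bp; 42 and 21 of 10000 random sets of 16 such intervals were covered as little. By the number of intervals with a peak, 565 and 95 sets were as low, so the H3K4me3 count of 6 did not stand apart. The 5 kb on either side of the gaps were covered at 33.7% by H3K4me3 and 26% by H3K4me2. No peak of either mark touched the silent mating cassettes HML (chromosome III, 12386 to 13809) and HMR (293179 to 294321) or the MATALPHA genes of the reference, with the nearest peaks at least 1678 bp away. The cassettes and MAT share sequence, so reads there may not be placed uniquely. BY4741 is of mating type a and lacks the MATALPHA genes at MAT, so their lack of peaks says nothing about that locus. Of 275 nuclear tRNA genes 0 were touched by an H3K4me2 peak, which allows a share of up to 1.09%, and 2 by an H3K4me3 peak (0.727%, exact 95% interval 0.0882 to 2.60). Shifted positions gave at least 21.5 and 25.8%. Of 76 snoRNA genes 5 were touched by H3K4me2 (6.58%; shifts at least 15.8%) and 13 by H3K4me3 (17.1%; shifts at least 19.7%). These shifts also fall inside protein-coding genes, and no shift limited to intergenic sequence was run. The bases of the 1332 intergenic intervals, a measure unlike the share of genes touched, were covered at 7.29% by H3K4me2 and 14.0% by H3K4me3. The low snoRNA shares may therefore follow from position, which was not tested. The ribosomal DNA copies of the reference held 1 peak of each mark, from 459675 to 460677 on chromosome XII, over RDN5-1 and the sequence towards RDN37-2, and it was the only peak with the same start and end in both lists. Reads from these repeated copies may not be placed uniquely either, so this peak need not reflect the marks, which was not tested.

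As a check on strain and mapping, the genes that BY4741 lacks were examined, although 30.3% of all genes carried neither mark at the start. LEU2, URA3 and MET17 (also named MET15), which are deleted in this strain by its published genotype, had no base of their start windows under a peak of either mark. HIS3, which is only partly deleted, had an H3K4me3 peak over 80.4% of its start window (3.14-fold, 200 tags) and no H3K4me2. Of 10000 random lists matched on gene length, 806 were as low for H3K4me2 and 868 for H3K4me3. The 4 genes did not stand apart, so these absences cannot settle strain or mapping.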

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

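The tests on gene length, on single-copy genes, on genes matched by H3K4me3 fold, on library depth, on nucleosome loss and without RPP1 were chosen after the result was seen, and the low count already bounded the outcome of most of them. Those on gene length and nucleosome loss repeat the comparisons that flagged the cytosolic ribosomal protein list, so their outcome was fixed. 2 gene lists lay below random lists for one mark and above them for the other. Cytosolic ribosomal protein genes had H3K4me2 over 0.725% of starts and H3K4me3 over 75.4%. Mitochondrial ribosomal protein genes had H3K4me2 over 19.4% of starts and H3K4me3 over 79.1%. With 1 library per mark the difference between marks was not tested.

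Cytosolic ribosomal protein genes had H3K4me2 at 0.725% of starts, below the 31.9 to 46.4% of length-matched random lists. That comparison flagged the list, so it is no separate test of short gene length. Loss of reads shared between duplicated copies does not account for the low H3K4me2. Of the 20 single-copy members 5% carried it (random lists 15 to 55%, and 0 of 19 without RPP1) and 90% carried H3K4me3. A shift beyond these short genes does not account for it either. H3K4me2 covered 11.5% of the 500 bp that begin 750 bp after the start (random lists 27.6 to 40%). Among starts with H3K4me3, 0.962% of ribosomal protein genes had H3K4me2 against 48.1 to 64.4% of other genes of the same library matched on length and H3K4me3 fold, which argues against low library depth alone and against a general feature of short genes with strong H3K4me3. Loss of nucleosomes over the first 500 bp of the gene alone would lower H3K4me3 there as well. H3K4me3 lay at 75.4%, above the 56.5 to 71.7% of random lists, but this value also flagged the list and is no separate test. With 500 bp upstream included, the H3K4me3 difference from random lists was -21.1 points. Loss of nucleosomes that reaches upstream therefore stays open, as do the background used for the H3K4me2 peaks and combinations of these explanations, and no biological explanation was tested.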

How the results depend on the processing

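No paired analysis was possible because each mark has 1 library, and for the same reason no library could be left out. The false discovery rate limit was not run, since the lists hold no such column. Of 136 main values under 11 alternatives 81 stayed within their interval or, for counts, within 1.5 times. With a score of at least 100, H3K4me2 covered 22.2% of the span and H3K4me3 28.1%, the overlap was 84.4% of H3K4me2 and 59.5% of H3K4me3 peaks, marked starts were 33.4 and 55.0%, half-maximum positions were 1400 and 940 bp, the median distance between marks was 209 bp, marked ends were 15.3 and 3.78%, and 2 checkpoint genes had H3K4me2. With the same number of peaks in both lists, the overlaps were 78.0 and 76.2%, so most of the gap between the directions follows list length; H3K4me3 starts were 53.9%, starts with H3K4me2 alone 521, the H3K4me3 half-maximum 940 bp, H3K4me3 ends 3.69% and checkpoint genes with H3K4me3 5. With 500 bp peaks, coverage was 12.4 and 15.4%, overlaps 68.2 and 55.1%, half-maxima 930 and 570 bp, the median distance 298 bp, H3K4me2 downstream in 89.2%, and ends 2.94 and 1.96%. Requiring 50% of a peak gave overlaps of 82.1 and 66.9%, and reciprocal 50% gave 74.9 and 60.5%. With peaks at or above the median fold, starts were 23.0 and 34.5%, with 846 under both marks, 537 under H3K4me2 alone and 3393 under neither. With 1 bp of the window H3K4me2 starts were 50.1%; with the whole gene, starts were 51.5 and 66.5%. With a window of 500 bp on both sides, starts were 24.3 and 61.1%, with 1204 under both and 2464 under H3K4me3 alone. In genes of at least 3000 bp, half-maxima were 1140 and 810 bp, the median distance 163 bp, H3K4me2 downstream in 97.8%, and ends 3.04 and 1.52%. Lists above random for H3K4me2 numbered 1 with the fold limit and 2 with 1 bp, the window on both sides or the whole gene. Of 322 list values 294 kept their call, 22 lost it and 4 gained one in the same direction. The other 2 changed sign, both with the window on both sides: cytosolic ribosomal proteins for H3K4me3 reversed their call (-21.1 points), and ribosome biogenesis for H3K4me2, within the random range before, fell below it (-14.6 points). For these 2 the cause was not tested. The total depth of each library is unknown, so its effect on the numbers of peaks was not measured.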

Other observations

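The tests on transcripts within 500 bp of gene ends and on tRNA flanks 100 to 400 bp away, and the summit positions, were chosen after the results were seen, as were the genes and transcripts named. Few long genes carried H3K4me3 at their end and not at their start, 28 of 2248 genes of at least 1500 bp (1.25%), and 22 of them had H3K4me2 over the end too. They included ACS1 (acetyl-CoA synthetase), CYB2 (lactate dehydrogenase) and MLS1 (malate synthase), which are 3 of the 13 glucose-repressed genes of that length (23.1%). The pattern requires a start without H3K4me3. H3K4me3 lay at the start of 3 of 18 glucose-repressed genes and of 1575 of the 2248 long genes. Part of the higher share therefore follows from the definition. Also among the 28 were the catalase gene CTA1, the glycogen-branching enzyme gene GLC3, the respiratory regulator gene HAP4, the galactose activator gene GAL4, and the meiotic genes IME4 and SPO22. Of the 7 transcripts annotated as antisense, 5 had both marks over their first 500 bp (exact 95% interval 29.0 to 96.3%), among them RME2, which lies against IME4, and YNCP0002W, which lies against GAL4. RME3 and YNCM0001W had neither. By any overlap, 6 of the 7 were touched by each mark (85.7%), and shifted positions gave 14.3 to 100%, with means of 64.8% for H3K4me2 and 71.5% for H3K4me3, so by overlap these transcripts did not stand apart from chance.

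The widest H3K4me3 peak, 5613 bp on chromosome XIII (241941 to 247553, 2689 tags), spanned 5 genes, TAF11, TRM9, UBX2, ERV25 and RAD33. The widest H3K4me2 peak, 3105 bp on chromosome II (462760 to 465864, 1776 tags), lay over the single gene CYC8, which encodes a general corepressor. Of genes with H3K4me2 alone at the start 17 of 306 lay within 20 kb of a chromosome end (5.56%, exact 95% interval 3.27 to 8.75), close to the 4.22% of all 6002 genes (3.72 to 4.75). The share was 0.763% for H3K4me3 alone (0.395 to 1.33), 1.17% for both marks (0.773 to 1.70) and 10.8% for neither (9.45 to 12.4), and these differences were not tested. Peak summits lay a median of 290 bp after the nearest start codon for H3K4me3 (bootstrap 95% interval 281 to 299) and 531 bp after it for H3K4me2 (522 to 545).

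The H3K4me3-marked ends of genes without H3K4me3 at the start may come from the start of a neighbouring gene. Another protein-coding start lay within 500 bp of the end window in 46.4% of the 28 genes (exact 95% interval 27.5 to 66.1), against 32.3% of long genes without H3K4me3 at the end (30.3 to 34.3). These intervals overlap, and 15 of the 28 had no such neighbour, so this stays open for part of them. An annotated non-coding transcript began in the end window in 0% and within 500 bp of it in 7.14% (IME4 and GAL4, by RME2 and YNCP0002W), so annotated ones do not account for most. Only 7 transcripts are annotated as antisense, so these shares were bound to be low and say little about antisense transcription. Antisense transcripts outside the annotation stay a hypothesis that was not tested.

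The near absence of peaks over tRNA genes may come from reads lost over these repeated sequences. The test planned for this used the bases 500 to 1000 bp to either side, where H3K4me3 covered 29.2%, inside the 28.1 to 36.1% of shifted positions, as that explanation requires. A closer zone, added once this was known, lay below shifted positions: H3K4me3 covered 12.9% of the bases 100 to 400 bp away against 27.5 to 36.7%. Shifts also move these zones into genes, however. Of the bases in 1332 intergenic intervals of 630 to 2541 bp outside the centromeric gaps, H3K4me3 covered 14.0%. The low value may therefore follow from a position between genes, and it cannot decide on read loss. Read loss stays open for the tRNA genes themselves. For the nearby zone a position between genes, other repeats, fragment length and few nucleosomes stay open. No biological explanation was tested.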
